A study of Mus musculus with 5 samples.

How the data were processed

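Rbpj was profiled by CUT&RUN in 5 libraries of primary mouse keratinocyte cultures, 1 per condition. Groups were taken from the sample titles: WT, WT with EDTA, WT with an Adam10 inhibitor, Ajuba knockout, and Ajuba knockout with EDTA. The treatment field of the labels gives 30 min of EDTA and 15 min of recovery for all 5 samples, including those whose titles name no EDTA. The dose and duration of the Adam10 inhibitor, the way Ajuba was knocked out and the number of animals or cultures are not given in the sources used here.

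HISAT, Picard, bedtools and MACS2 and the builds mm10 and GRCm38 are named in the submitters' processing notes, without versions, roles or order. For each region the deposited files give 2 values of coverage signal, read from the values as the area under the track and its maximum. The 5 files hold the same 6957 regions, so the regions were set once for all libraries. How the regions were chosen, and how the tracks were scaled, is not given in the sources used here. A region chosen because of a high value in 1 library tends to have a lower value in the others, whatever the condition.

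The deposited maxima were whole multiples of 1 step, less whole multiples of a second step, within a tolerance of 0.002. The step of 1 fragment was 1.01 in WT, 0.843 in WT with EDTA, 0.995 with the Adam10 inhibitor, 0.661 in the knockout and 0.743 in the knockout with EDTA. The second step, read as a subtracted background, was 0.860, 0.150, 0.0922 and 0.475 in the libraries other than that with the Adam10 inhibitor, whose values showed no subtraction. It is known only up to a multiple of the step of 1 fragment, so a subtracted step larger by 1 fragment was an alternative. Larger multiples were not tried. A subtraction of whole fragment steps in the library with the Adam10 inhibitor would not be seen. The number of fragments at each maximum was recovered from these steps. These are overlapping fragments at 1 position, not counts of reads, and no count test was run on them. In the library with the Adam10 inhibitor, 14 regions had no value and were read as 0; 6, 127 and 112 regions were at 0 in WT with EDTA, the knockout, and the knockout with EDTA.

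Areas were divided by the list total, and log2 ratios were computed with a pseudocount of 50 added to the scaled area, which understates changes of low regions. A fold of totals is the ratio of summed areas as deposited. Intervals of a ratio of totals are 95% ranges over 1000 resamplings of the regions. Exact 95% intervals of a ratio of fragments served to select named regions. Counting error alone was simulated 100 times, by drawing Poisson fragments with 1 common ratio for all regions. Fragments were compared after adding 0.5, in the data and in the simulation alike. The data are maxima of chosen regions, which need not vary like Poisson counts, so the simulated shares are no floor for the observed ones. No test between conditions and no p-value was computed, since each condition has 1 library. Comparisons were knockout with WT without EDTA, the same with EDTA, EDTA with no EDTA in each genotype, and the Adam10 inhibitor with WT.

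A table of mouse genes of the assembly GRCm38.p6 gave the extent of 21896 protein-coding genes, without strand or transcription starts. Distances to transcription starts were therefore replaced by distances to gene extents: a gene has a region if one lies within 5 kb of its extent, and a region is named by the protein-coding gene it overlaps or is nearest to within 100 kb. This held for 6695 of 6957 regions, and 3794 genes had a region within 5 kb. The shares of regions at promoters and with an RBPJ motif were not analysed here, for lack of transcription starts and sequence. Regions were also shifted 1000 times along their chromosomes. Gene lists were fixed before the data were examined, together with the comparisons and a set of alternative settings: Notch targets, Notch pathway, suprabasal differentiation, basal keratinocyte, Hippo and YAP targets, head and neck tumour suppressors, AP-1 and immediate early genes, fibroblast markers, melanocyte, immune and endothelial markers, and housekeeping genes. All 225 list members matched the table. Some genes stand in more than 1 list. The number of list members with a region was set beside 10000 random lists matched on gene length, and list medians beside 10000 random lists matched on mean area.

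The planned rule for named genes took peaks found in only 1 list of a comparison, of which there were none because the regions are shared. A rule written after the layout of the files was seen, and before any region was matched to a gene, took its place: per comparison, the 10 largest rises and 10 largest falls of the relative area, among regions where the maximum moved the same way and the 95% interval of the fragment ratio lay on that side of the ratio of totals, and the 5 strongest regions of the first library. Members of the fixed lists with a region were named in addition; the values of some single genes are not reported here. Chromosome medians were set beside 1000 random draws of as many regions, and 10 Mb intervals were examined on chromosomes 5 and 18, chosen after seeing the chromosome medians.

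The recovery of fragments, changes of regions, shifts of chromosomes, gene lists and the position at gene ends were checked on simulated data; the other steps were not. Recovery from the steps returned 100% of simulated fragments in each library. Any simulated subtracted step was smaller than the step of 1 fragment. This check therefore does not show which multiple was subtracted in the data. Of 200 regions changed 4-fold, 100 in each direction, the share that came out at least 2-fold changed was 93% for raised and 79% for lowered regions in the comparison of knockout with WT, 93% and 83% in the same comparison with EDTA, 98% and 93% for EDTA in WT, 85% and 62% for EDTA in the knockout, and 96% and 85% for the Adam10 inhibitor. A chromosome raised by 1 on the log2 scale came out at 0.88 to 1.07, and a gene list raised by 1 at 0.87 to 1.02, above all random lists. Of 10 lists set against randomly placed genes, 10 lay inside the central 95% of random lists. Alternatives were division by the list median, other windows and merging of regions, the upper 50% of each list, values as deposited, the maximum, recovered fragments with and without the scaling of the tracks, a pseudocount of 10, and leaving out chromosomes 5, 18 and X. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.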

Results

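Rbpj is the DNA-binding factor through which Notch receptors act on transcription. Its occupancy was profiled by CUT&RUN, in which an antibody directs a nuclease to cut out the DNA around a bound protein, in primary cultures of mouse keratinocytes. The series comes from a study of NOTCH regulators that restrain head and neck squamous cell carcinoma, and asks which Rbpj sites differ between Ajuba wild-type (WT) and Ajuba knockout cells. Ajuba is a LIM-domain scaffold protein. There were 5 libraries, 1 per condition: WT, WT with EDTA, WT with an Adam10 inhibitor, Ajuba knockout, and Ajuba knockout with EDTA. These are the conditions of the sample titles; the treatment field of the labels gives EDTA for all 5. EDTA chelates calcium and releases the Notch ectodomain, and Adam10 is the metalloprotease that cleaves ligand-bound Notch. With 1 library per condition no difference between conditions could be tested against replicate error, and each comparison describes a pair of libraries.

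The 5 files gave a signal for the same 6957 regions of the mm10 genome, with a median width of 184 bp and a range of 100 to 1762 bp. The mean area under the coverage track per region was 1425 in WT, 1652 in WT with EDTA, 889 with the Adam10 inhibitor, 722 in the knockout and 616 in the knockout with EDTA. The number of sequenced reads is not given in the sources used here. The steps between the deposited maxima gave a median of 9, 11, 5, 7 and 6 overlapping fragments at the maximum of a region in these libraries, in the same order. A single region therefore carried few fragments, and all counting intervals cover counting error only.

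**Figure D1:**
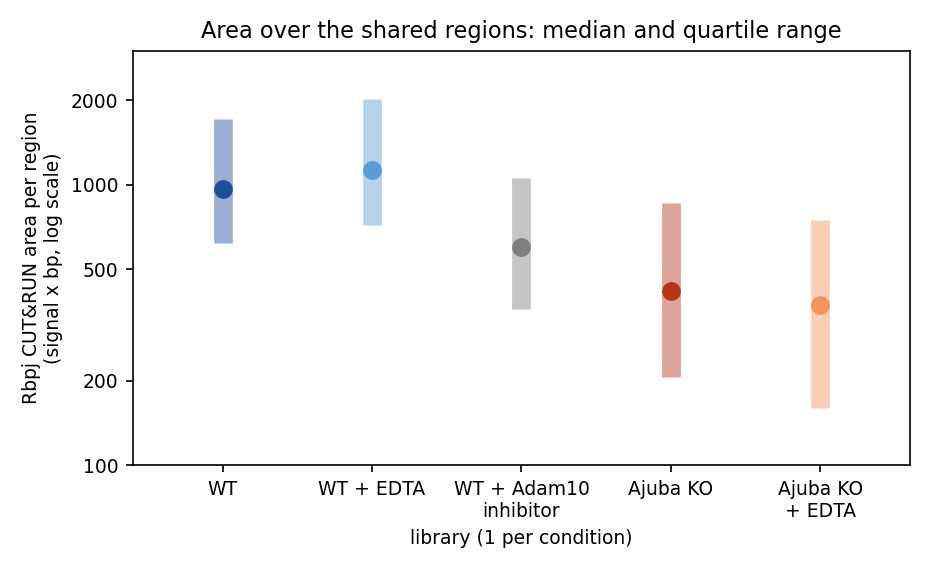
Area under the Rbpj CUT&RUN track per region (log axis, signal times bp) in the 5 libraries over the same 6957 regions; points are medians and bars run from the lower to the upper quartile. The median lay at 967 in WT and 1124 in WT with EDTA, and at 416 and 372 in the knockout without and with EDTA.

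A region lay within 5 kb of 3794 protein-coding genes. Such a region can lie in a neighbouring gene. The only region counted for Hes7, and the strongest ones counted for Sfn and Zfp36, lay outside these genes and overlapped another protein-coding gene. Of 24 basal keratinocyte genes, 19 had a region, against a mean of 4.65 in random gene lists of matched gene length. They included Krt5 and Krt14, the keratins of the basal layer, the integrin genes Itga3, Itga6, Itgb1 and Itgb4, and Jup, which encodes plakoglobin. Of 24 AP-1 and immediate early genes, 17 had a region, against 3.84 in random lists, with 12 regions at Junb and 10 at Zfp36. Among 25 Notch target genes, 13 had a region, against 4.44 in random lists. Hes1, a repressor induced by Notch, had 9 regions, and Nrarp, a Notch target that limits Notch signalling, had 3.

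A region was also found at 13 of 34 Notch pathway genes (random mean 6.69), 9 of 24 suprabasal differentiation genes (4.06), 9 of 20 Hippo and YAP target genes (3.89) and 10 of 22 tumour suppressor genes of head and neck cancer (4.35). It was found at 6 of 20 housekeeping genes (3.46). Marker genes of other cell types lay near the random level: 1 of 15 fibroblast markers (2.78), Col1a1, and 2 of 17 melanocyte, immune and endothelial markers (3.12), Pmel and Cd68. Across the genome, 29.9% of regions (exact 95% interval 28.9 to 31.0) lay within 1 kb of an end of a protein-coding gene, against a mean of 3.35% and a highest value of 4.48% in 1000 shifted sets. Regions were ranked by area, which grows with their width. The strongest region of WT, WT with EDTA, the Adam10 inhibitor library and the knockout was the same one, at Slc29a2, a nucleoside transporter gene (chromosome 19, 5017466 to 5019128). In the knockout with EDTA it was a region at Plec, which encodes plectin, a linker of hemidesmosomes (chromosome 15, 76195633 to 76197356). In fragments at the maximum, other regions stood higher in the knockout (up to 32, against 26 at Slc29a2). The same held in the knockout with EDTA (up to 33, against 21 at Plec).

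Ajuba itself had 2 regions within 5 kb of the gene. Their summed area was 2179 in WT, 2113 in WT with EDTA, 1351 with the Adam10 inhibitor, 1399 in the knockout and 1174 in the knockout with EDTA. The part of Ajuba that was deleted is not given in the sources used here, so these values do not check the genotype of the libraries. The 1 region at Adam10 had areas of 286, 741, 212, 312 and 125 in the same order.

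**Figure D2:**
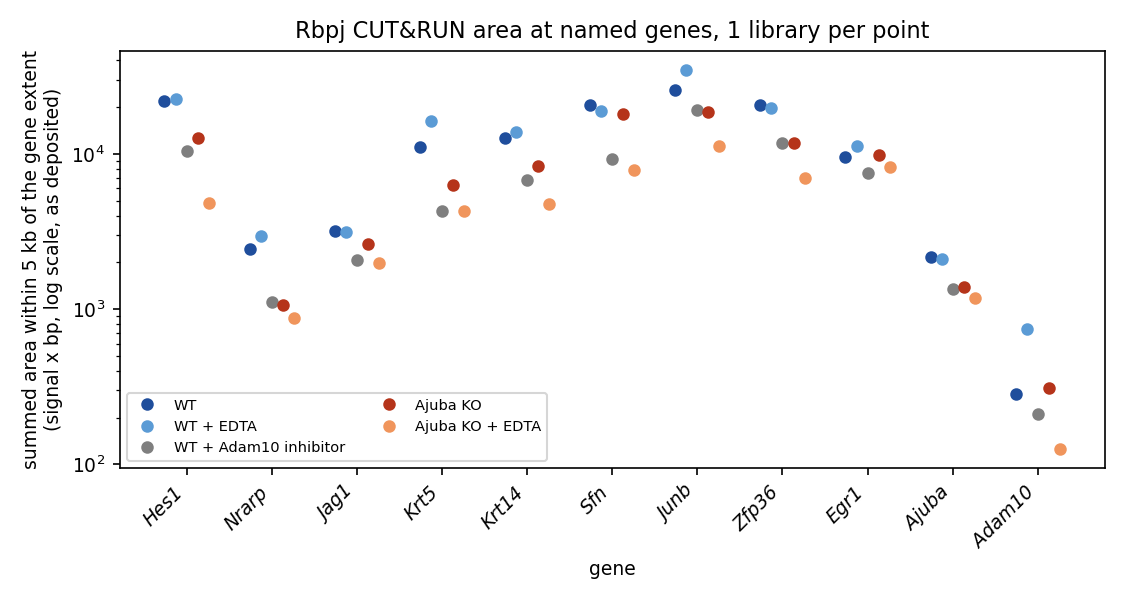
Summed area of the regions within 5 kb of each gene (log axis, signal times bp, as deposited) in the 5 libraries, 1 point per library. At Hes1 the area was 21915 in WT and 4841 in the knockout with EDTA, and at Ajuba it was 2179 and 1174.

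Between the 2 libraries whose titles name no treatment, the Rbpj signal was lower in the knockout than in WT at most regions. At Hes1 the area was 21915 in WT and 12660 in the knockout, at Krt14 12707 and 8375, at Krt5 11002 and 6332, and at Nrarp 2444 and 1065. The summed area was 1.97-fold lower in the knockout, and 6312 of 6957 regions (90.7%) had the lower value there. The log2 ratio of totals was -0.98, with an interval of -1.003 to -0.957 from resampling regions, which leaves out any spread between cultures. Part of this ratio comes from the scaling of the tracks, in which 1 fragment counted 0.661 in the knockout and 1.01 in WT: in recovered fragments without this scaling the log2 ratio was -0.37. Neither the basis of the scaling nor the sequencing depth is given in the sources used here. Changes of single genes are given below relative to this ratio of totals, so that a value of 0 means a gene that followed the total.

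Relative to the total, the 13 Notch target genes with a region had a median log2 ratio of 0.20, at percentile 75.045 of random gene lists of matched area, so the list did not stand apart from other genes. Notch1 stood at 0.76, Jag1 at 0.68 and Nfkb2 at 0.92, while Cdkn1a stood at -0.77 and Hey2 at -0.65. The median of the 9 suprabasal differentiation genes was 0.55, at percentile 98.9, with 6 genes above 0. Among them were the transcription factor genes Cebpb (0.99), Grhl3 (0.72) and Ovol1 (0.55), and Ppl (0.99), which encodes the cornified envelope protein periplakin. The 3 genes below 0 were Tgm1 (-0.15), Sprr3 (-0.18) and Evpl (-0.22). As deposited, without the division by the totals, the signal at Grhl3 was still lower in the knockout (2898 against 3440) and that at Ppl was close (2124 against 2074). Other list medians lay inside the central 95% of random lists, at 0.12 for basal keratinocyte genes, 0.20 for the Notch pathway, -0.09 for Hippo and YAP targets, 0.28 for tumour suppressors, 0.02 for immediate early genes and -0.44 for housekeeping genes.

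Among single regions, 7 of the 10 largest falls were listed at 0 in the knockout. They included a region in Dock8 (chromosome 19, 25172071 to 25172413), with an area of 2609 and 11 fragments in WT, and one nearest to Irs2, an insulin receptor substrate gene, with an area of 2070 in WT. Runx1, a transcription factor gene, held a region with an area of 2160 in WT and 7.97 in the knockout. The largest rises included 2 regions in Impa2, with areas of 729 and 866 in the knockout against 38.3 and 75.1 in WT, and regions in Impact (629 against 46.4), Kdm3b (596 against 83.7) and Zdhhc18 (686 against 115). Impa2, Impact and Kdm3b lie on chromosome 18. Of all regions, 7.43% were at least 2-fold higher and 21.9% at least 2-fold lower relative to the totals; the shares were 12.5% and 17.8% after division by the list medians, and 1.11% and 53.6% as deposited. Counted in recovered fragments, 12.6% were at least 2-fold lower, against 9.03% in simulations with counting error alone, and 5.48% were higher, against 8.82%. Observed shares below the simulated ones, here and in other comparisons, mean that the simulation is no floor for these maxima. The excess of lower regions over it was therefore not interpreted.

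With EDTA in both libraries, the knockout again had the lower signal. At Hes1 the area was 22499 in WT with EDTA and 4841 in the knockout with EDTA, at Krt5 16221 and 4259, at Sfn, the stratifin gene, 18989 and 7896, and at Junb 34803 and 11194. The summed area was 2.68-fold lower in the knockout (log2 ratio -1.42, resampling interval -1.45 to -1.40), and 97.7% of regions had the lower value there. On the maxima as deposited the log2 ratio of totals was -1.11, on fragments at the maxima with the subtracted background undone it was -0.99, and without the scaling of the tracks as well it was -0.81.

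Relative to the total, the Notch target list had a median of -0.19, at percentile 9.33, with Hes1 at -0.79, Lfng at -0.77 and Hey2 at -0.70, and with Cdkn1a at 0.92 and Jag1 at 0.75. In recovered fragments this median was 0.11, at percentile 55.5. No list median lay outside the central 95% of random lists in this comparison. The medians were -0.26 for the Notch pathway, 0.00 for suprabasal differentiation, -0.13 for basal keratinocyte genes, -0.31 for Hippo and YAP targets, -0.09 for tumour suppressors, -0.07 for immediate early genes and 0.04 for housekeeping genes. The largest falls included regions nearest to Cnot2 (area 2315 against 13.1), Id1, an inhibitor of differentiation gene (1692 against 9.11), Dennd2c (1542, listed at 0 in the knockout) and Cldn4, a tight junction gene (1243, listed at 0). The largest rises were nearest to Mlph (642 against 12.5), Sema3e (361 against 0.273), Ccbe1, with 2 regions, Zfp438, with 2 regions, Zbtb7c and Sh3tc2. The last 4 genes lie on chromosome 18. The Sema3e region had an area of 563 in WT without EDTA, and was also among the largest falls with EDTA in WT.

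The 2 knockout comparisons have no library in common. Across the 6957 regions, their relative log2 ratios correlated with a Pearson r of 0.37 and a Spearman rho of 0.34; regions are not independent replicates. Both comparisons placed 672 regions at least 2-fold lower, where independent lists would share 342. They placed 85 regions at least 2-fold higher, where independent lists would share 27.2. This reference takes all regions as equally likely to change 2-fold, whatever their signal. None matched on area was computed, so the excess and the correlation only describe these libraries. The regions of Dock8, Irs2, Cnot2 and Dennd2c were among those lower in both. Of the 85 higher regions, 50 (58.8%) lay on chromosome 18, which holds 3.03% of all regions. Of the 672 lower regions, 167 (24.9%) lay on chromosome 5, which holds 11.4%. Without chromosomes 5, 18 and X, 494 regions were lower in both (249 for independent lists) and 30 were higher (16.8), and r was 0.34.

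Chromosome 18 stood apart in both knockout comparisons. The median log2 ratio of its 211 regions exceeded that of the other chromosomes by 0.97 without EDTA and by 0.99 with EDTA, and it was above 0 in each of its 9 intervals of 10 Mb in both. Egr1, an immediate early gene on chromosome 18, stood at 1.02 and 0.97 relative to the total, and Lama3, a laminin gene there, at 0.51 and 0.84. The 790 regions of chromosome 5 lay below the others by -0.64 and -0.49. Rbpj (-0.57 and -0.84), Lfng (-0.41 and -0.77) and Fosl2 (-1.30 and -0.99) are on chromosome 5. Mafk (-0.49 and 0.28) and Rplp0 (-0.32 and 0.15), also on it, stood above 0 with EDTA. Both chromosomes lay outside 1000 random draws of as many regions in both knockout comparisons. So did chromosome 4 (-0.21 and -0.21), chromosome 8 (0.21 and 0.19) and chromosome 11 (0.21 and 0.21), with smaller shifts, and chromosomes 6 and 17 without EDTA and 10 and 13 with EDTA. The 27 regions of chromosome X differed by -0.81 and -0.65, inside the draws. Neighbouring regions are not independent, and within a genotype chromosomes 3, 7, 11, 13 and 16 lay outside the draws in 1 comparison each. In the 3 comparisons within a genotype, the shift of chromosome 18 was -0.11, -0.11 and 0.09, and that of chromosome 5 was -0.11, -0.01 and 0.05.

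**Figure D3:**
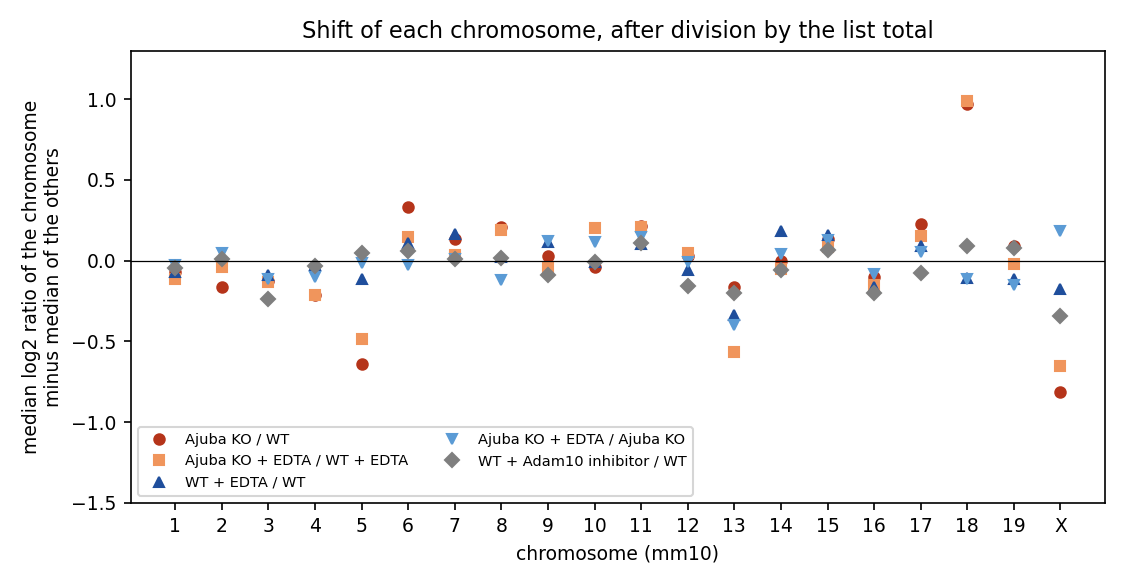
Median log2 ratio of the regions of each chromosome minus the median of the regions on all other chromosomes, after division by the list total, for the 5 comparisons; 1 point per comparison. Chromosome 18 stood at 0.97 and 0.99 and chromosome 5 at -0.64 and -0.49 in the comparisons of knockout with WT, and both lay within 0.2 of 0 in the comparisons within a genotype.

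In WT cells, the library with EDTA had a higher area at Krt5 (16221 against 11002), Junb (34803 against 25793) and Nfkb2 (10255 against 7002). It had a lower area at Atf3 (10600 against 16882), Dst, the dystonin gene (7718 against 12544), and Rbpj (6225 against 8965), and Hes1 was close (22499 against 21915). The summed area was 1.16-fold higher with EDTA (log2 ratio 0.21, resampling interval 0.20 to 0.23), and 61.8% of regions had the higher value. On the maxima as deposited the log2 ratio was 0.14. On fragments at the maxima with the subtracted background undone it was 0.018, and it ran from -0.14 to 0.14 with the size of the step that was taken to be subtracted; without the scaling of the tracks as well it was 0.28.

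Relative to the total, the 17 AP-1 and immediate early genes had a median of -0.31 with EDTA, at percentile 0.19 of random lists, with 13 of 17 genes below 0. Fos (-0.93), Atf3 (-0.88), Jun (-0.54) and Dusp1 (-0.53) were among those below 0, and Junb stood at 0.22 and Ier5 at 0.73. In recovered fragments the list median was -0.19, at percentile 0.605. The Notch target genes had a median of 0.05, at percentile 45.9, with Hes7 at 0.77, Nfkb2 at 0.33 and Hey2 at -0.73. The region counted for Hes7 overlaps a neighbouring gene. Medians of the other lists lay inside the central 95%: -0.20 for the Notch pathway, 0.13 for suprabasal differentiation, -0.08 for basal keratinocyte genes, -0.25 for Hippo and YAP targets, 0.04 for tumour suppressors and -0.21 for housekeeping genes. Single regions with the largest rises were in Cbx6 (734 against 12.3), Vps37c (1063 against 55.8) and Pld2 (662 against 25.8), and nearest to Sqle, the squalene epoxidase gene (2981 against 304). The largest falls included Nwd1 (863 in WT, listed at 0 with EDTA), Mob3b (1366 against 45.7) and Ahnak (682, listed at 0). Relative to the totals, 9.11% of regions were at least 2-fold higher and 10.4% at least 2-fold lower, against 14.7% and 7.60% as deposited; the shares in recovered fragments, 4.02% and 6.54%, were close to or below the 6.65% and 6.28% of counting error alone.

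In knockout cells, the area with EDTA was lower at Hes1 (4841 against 12660), Atf3 (2592 against 7709), Fosl1 (1871 against 4764), Sfn (7896 against 17981) and Junb (11194 against 18675). It was close at Jund (4483 against 4526) and Lama3 (5654 against 5610). At Ajuba it was lower (1174 against 1399), with a log2 ratio of -0.24 as deposited. The summed area was 1.17-fold lower with EDTA (log2 ratio -0.23, resampling interval -0.25 to -0.21). The log2 ratio was -0.11 on the maxima as deposited. It was 0.0082 on fragments at the maxima with the subtracted background undone, and ran from -0.17 to 0.21 with the size of the subtracted step; without the scaling of the tracks as well it was -0.16.

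Immediate early genes had a median of -0.49 relative to the total, at percentile 0.16 of random lists, with 11 of 17 genes below 0: Jun stood at -1.39, Fos at -1.34, Atf3 at -1.33 and Fosl1 at -1.11, and Dusp5 at 0.68 and Mafk at 0.77. In recovered fragments the median was -0.32, at percentile 0.63. This comparison and that of WT with and without EDTA have no library in common. Notch pathway genes had a median of -0.56, at percentile 0.30, with Spen, a corepressor gene, at -2.67, Kdm5a at -1.12 and Rbpj at -1.003, and Psen2 at 1.34; in recovered fragments the percentile was 11.3. For the Notch target genes the median was -0.24, at percentile 3.30, with Hes1 at -1.15, Hey2 at -0.79 and Cdkn1a at 0.83. The medians were -0.27 for suprabasal differentiation, -0.17 for basal keratinocyte genes, -0.02 for Hippo and YAP targets, -0.17 for tumour suppressors and 0.34 for housekeeping genes, all inside the central 95%. The largest rises included regions nearest to Mlph (642, listed at 0 without EDTA) and in Gapdh (281, listed at 0) and Cd274 (252, listed at 0), and the largest falls included Pclo (6.97 against 688), N4bp1 (12.9 against 594) and regions nearest to Il33 (334) and Hspa1a (332), both listed at 0 with EDTA. Relative to the totals, 13.7% of regions were at least 2-fold higher and 16.0% lower, against 8.55% and 18.8% as deposited. In recovered fragments 9.06% and 8.35% were, fewer than the 11.3% and 10.99% of counting error alone. The simulation therefore overstates the spread of these maxima.

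**Figure D4:**
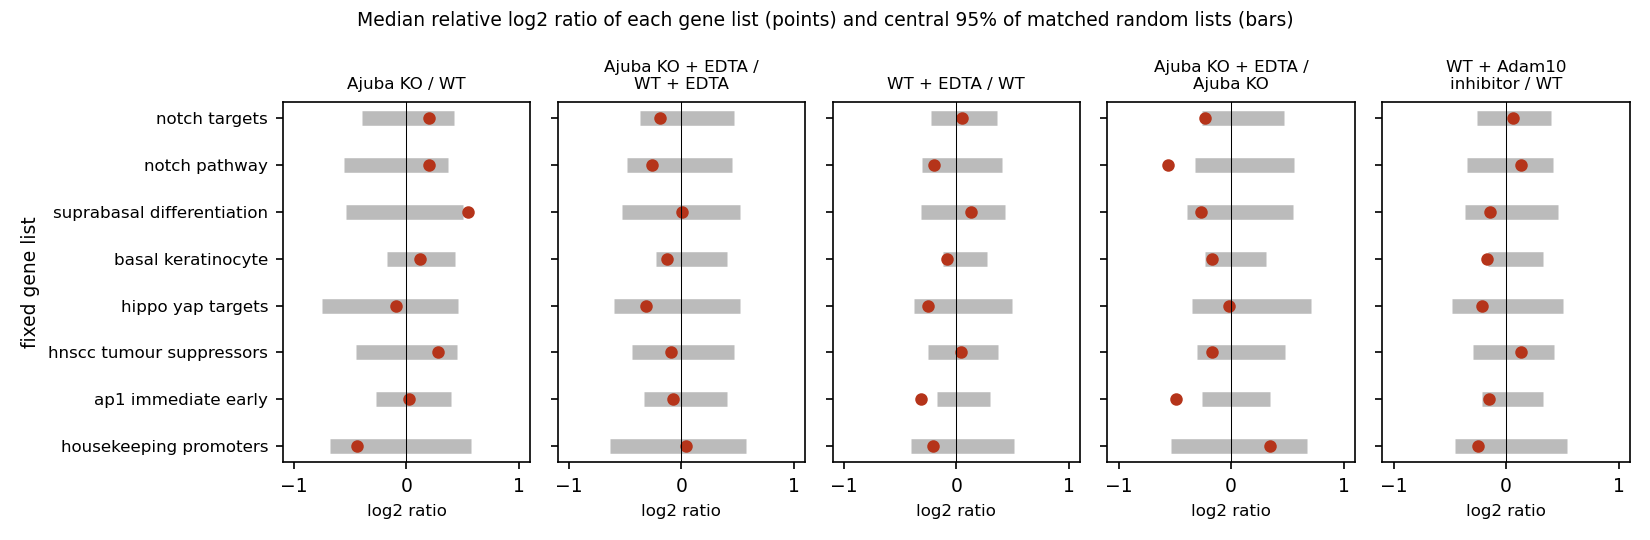
Median log2 ratio of each fixed gene list relative to the list total (points) and the central 95% of 10000 random gene lists matched on area (grey bars), for the 5 comparisons; lists with fewer than 3 genes with a region are left out. The immediate early genes stood at -0.31 and -0.49 in the comparisons of EDTA with no EDTA, outside the range of random lists in both.

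Across regions, the relative log2 ratios of EDTA in WT and in knockout cells correlated with a Pearson r of 0.19 and a Spearman rho of 0.20. Both placed 231 regions at least 2-fold lower with EDTA, against 116 for independent lists, and 150 at least 2-fold higher, against 87.0. As above, this reference is not matched on area. The change of totals with EDTA differed between the genotypes by 0.44 on the log2 scale, which could not be tested with 1 library per condition.

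With the Adam10 inhibitor, WT cells had a lower area at Hes1 (10363 against 21915), Nrarp (1106 against 2444), Krt5 (4275 against 11002), Tgm1, the transglutaminase gene of the cornified envelope (1094 against 4632), and Dst (4370 against 12544). Areas were closer at Zfp750, a regulator of epidermal differentiation (9906 against 12290), and Hes7 (3071 against 2647). The summed area was 1.60-fold lower (log2 ratio -0.68, resampling interval -0.70 to -0.66), and 81.4% of regions had the lower value. Unlike those of WT, the values of this library show no subtracted background, although a subtraction of whole fragment steps would not be seen. The log2 ratio was -0.63 on the maxima as deposited. It was -0.78 on fragments at the maxima with the subtraction in WT undone, and -0.76 without the scaling of the tracks as well.

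Relative to the total, the Notch target genes had a median of 0.06, at percentile 49.0, with Hes1 at -0.40, Nrarp at -0.45, Notch1 at -0.60 and Hes7 at 0.88. As above, the region counted for Hes7 overlaps a neighbouring gene. Basal keratinocyte genes had a median of -0.17, at percentile 2.33, with Itgb1 at -0.93, Dst at -0.83, Perp at -0.69 and Krt5 at -0.68. In recovered fragments this percentile was 4.35, inside the central 95% of random lists. Medians of the other lists lay inside that range: 0.13 for the Notch pathway, -0.14 for suprabasal differentiation, -0.22 for Hippo and YAP targets, 0.14 for tumour suppressors, -0.15 for immediate early genes and -0.25 for housekeeping genes. Of the 40 list medians computed over the 5 comparisons, 5 lay outside the central 95% of random lists, where chance gives 2. The largest falls included regions nearest to Lax1 (778 in WT), Ccl20, a chemokine gene (673), and Myh9 (666), all listed at 0 with the inhibitor. The largest rises included Cbx6 (480 against 12.3), Ndfip1 (588 against 88.6) and Col23a1 (1012 against 223). The Cbx6 region was also among the largest rises of the other 2 comparisons against the same WT library, which held 1 fragment there. Relative to the totals, 9.54% of regions were at least 2-fold higher and 9.98% lower, against 2.49% and 33.2% as deposited. In recovered fragments 6.80% and 7.56% were, fewer than the 10.05% and 10.7% of counting error alone. The simulation overstates the spread here too.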

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

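The ratios of summed areas and the medians of the Notch target list follow comparisons and a list fixed in advance; the other tests in this part were chosen after the result they bear on had been seen. The comparison of EDTA with no EDTA gave opposite signs in the 2 genotypes: the log2 ratio of summed areas was 0.21 in WT cells and -0.23 in knockout cells, and the difference between them was not tested, with 1 library per condition. The second step of the maxima, read as a subtracted background, was 0.860 in WT, 0.150 in WT with EDTA, 0.0922 in the knockout and 0.475 in the knockout with EDTA. Each is known only up to a multiple of the step of 1 fragment. Unequal subtraction is therefore a candidate explanation. The difference between genotypes was 0.44 on areas, 0.25 on the maxima as deposited, and 0.0097 on the fragments at the maxima with the subtraction undone, so the measure takes part in the change. Over the steps tried, this last value ran from -0.35 to 0.31, and in fragments without the scaling of the tracks from 0.081 to 0.74. Subtraction, scaling and a biological difference in the response to EDTA therefore cannot be told apart.

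The signal over the regions was lower in both knockout libraries than in the matched WT libraries. Choice of the regions for high signal in WT argues for a ratio near 0 in regions picked on other libraries. In the upper 25% of regions of each library outside the comparison the log2 ratio of totals was -0.69 or lower. Over all regions it was -0.98 without EDTA and -1.42 with EDTA. The upper 25% was taken from the same regions, so a choice made on WT stays in it and cannot be excluded. On fragments at the maximum with the subtraction undone, the ratio nearest to 0 over the steps tried was -0.79. Unequal subtraction of those sizes does not account for the lower signal, but steps larger by more than 1 fragment were not tried. In fragments without the scaling of the tracks the ratio nearest to 0 over the steps tried was -0.61 with EDTA and -0.20 without EDTA. Such fragments also depend on the sequencing depth, which the scaling may correct for. Neither the depth nor the basis of the scaling is known, so the scaling and a lower signal cannot be told apart, with or without EDTA. A loss at Notch target genes beyond that at other genes was not resolved: the lower percentile of the list median was 9.33, over 13 genes, and the other was 75.045, and in recovered fragments they were 55.5 and 87.4. A lower efficiency of the knockout libraries and an effect of the genotype cannot be told apart, because there was only 1 library per genotype and treatment.

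Regions on chromosome 18 were higher and regions on chromosome 5 lower in both knockout libraries, relative to the totals. Choice of the regions argues for no shift in regions picked on the Adam10 inhibitor library. There the smaller shift of the 2 comparisons was 0.71 on chromosome 18 and -0.44 on chromosome 5. These regions were picked from the same set, so the values do not exclude choice of the regions. On fragments at the maximum with the subtraction undone, the smaller shifts were 0.68 and -0.32, where areas gave 0.97 and -0.49. Subtraction of the smallest step therefore does not account for the whole shift. Larger steps were not tried for these shifts, so the subtracted background is not excluded. Within a genotype the shift of the whole chromosome farthest from 0 was -0.11 on chromosome 18 and -0.11 on chromosome 5, although intervals of both shifted. A difference in chromosome copy number between the WT and knockout cultures may account for this, but so may any other stable difference between them. The values do not single out copy number. On chromosome 5, the intervals from 0 to 10 and 10 to 20 Mb stood at -0.31 and -0.02 without EDTA and at 0.01 and 0.26 with EDTA. Its other intervals were below 0. No DNA control was analysed here, and an effect of the genotype on these chromosomes stays open and untested.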

How the results depend on the processing

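Division by the list median, the upper 50%, the 1000 highest regions, other definitions of overlap, merging of regions closer than 1 kb, autosomes only, and gene windows of 1 kb and of 10 kb were fixed in advance; every other alternative was chosen after seeing the data. Of 344 alternative values, 242 moved by less than their spread or by less than 1.5 times. Among those of the main results, such as totals and shares of changed regions, 73 did so, 64 moved further and 7 reversed. The 73 include overlaps that were fixed at 100% because the regions are shared. All 7 reversals concern EDTA and use fragments at the maximum with the subtraction undone, and no list median outside the random range reversed. The knockout ratios of totals kept their sign throughout, and so did that of the Adam10 inhibitor. The regions are the same in all files, so overlap is 100% under every definition of overlap. The upper 50% of regions were shared at 76.3% for the knockout and WT, 79.0% for both with EDTA, 80.4% for EDTA in WT, 78.4% for EDTA in the knockout and 77.8% for the Adam10 inhibitor, where independent lists would share 50%. For the 1000 highest regions the shares were, in that order, 73.1%, 72.4%, 76.2%, 74.9% and 72.6%, where independent lists would share 14.4%. For the totals, the maximum gave log2 ratios of -0.86, -1.11, 0.14, -0.11 and -0.63. Recovered fragments gave -0.99 for the knockout with EDTA, 0.018 for EDTA in WT, 0.0082 for EDTA in the knockout and -0.78 for the inhibitor. A larger subtracted step in both libraries gave -0.92, -0.013 and 0.031 for the first 3 of these. With the larger step in the first library only, the 4 comparisons other than the inhibitor gave -0.80, -0.79, 0.14 and 0.21, and with it in the second library only all 5 gave -1.14, -1.12, -0.14, -0.17 and -0.94. In recovered fragments without the scaling of the tracks the 5 ratios were -0.37, -0.81, 0.28, -0.16 and -0.76, so the size of the knockout ratios depends on the scaling. Without chromosomes 5, 18 and X the ratio was -0.95 for the knockout and 0.23 for EDTA in WT. In the upper 25% of regions of 1 outside library it was -0.79, -1.30, 0.24, -0.27 and -0.65, and of another -0.69, -1.24, 0.23, -0.31 and -0.65. The difference of the EDTA ratio between genotypes was 0.25 on the maximum, 0.0097 on recovered fragments and -0.044 with the larger step. It ran from -0.35 to 0.31 over the steps tried, and was 0.51 in the upper 25% of regions of the inhibitor library. Shares of regions at least 2-fold higher relative to the totals became 12.5% and 8.21% after division by the list median in the knockout comparisons without and with EDTA. As deposited they became 1.11%, 0.230%, 14.7%, 8.55% and 2.49%. On recovered fragments they became 4.25% for EDTA in WT and 6.17% for the inhibitor. Shares at least 2-fold lower became, as deposited, 53.6% and 73.8% in the knockout comparisons and 33.2% for the inhibitor. They became 14.2% on the maximum in the knockout comparison without EDTA, and 13.2%, 13.5%, 6.54% and 10.6% on recovered fragments in the first 4 comparisons. These shares of recovered fragments add 0.25 to the scaled value, and differ from those set beside counting error in the report, which add 0.5 to the number of fragments. With 0.25 added, counting error alone gave 9.99%, 11.6%, 6.28%, 12.9% and 12.5% lower and 8.82%, 7.77%, 7.06%, 11.6% and 9.31% higher. Values as deposited move these shares because the totals differ; the cause of the other changes was not tested. For list medians, 104 of 120 alternatives moved by less than the spread of random lists. Of the 5 medians outside the random range, 4 stayed outside without chromosomes 5, 18 and X. In gene extents alone, the number of members with a region was 7 against 13 for Notch targets, 6 against 13 for the Notch pathway, 2 against 9 for suprabasal differentiation, 5 against 9 for Hippo and YAP targets and 10 against 17 for immediate early genes. Within 1 kb that of suprabasal differentiation was 5, and within 10 kb that of fibroblast markers was 2 against 1. In the upper 50% of regions it was 8 for the Notch pathway in the knockout, 5 for Hippo and YAP targets with the Adam10 inhibitor, 3 against 6 for housekeeping genes in WT with EDTA and with the inhibitor, and 0 in the knockout and 1 in the 3 WT libraries against 2 for melanocyte, immune and endothelial markers. Not run were the promoter and motif shares and their alternatives, and windows around transcription starts, which were replaced by windows around gene extents; gene body and 10 kb upstream was run as 10 kb either side. With 1 library per condition no library could be left out. Single regions rest on few fragments, with 5 to 11 at the maximum of a median region.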

Other observations

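The test in this part was chosen after the result was seen. Outside chromosomes 5, 18 and X, the regions lower in both knockout comparisons included 1 nearest to Btg2, an antiproliferative gene induced by p53, with an area of 2014 in WT and 34.1 in the knockout, and 2075 and 88.2 with EDTA. Others were nearest to Arid5b (4864 and 157, and 1306 and 19.8 with EDTA), Hivep3 (1898 and 62.1, and 829 and 0 with EDTA) and Cd34, a marker of hair follicle stem cells in mouse skin (1035 and 0, and 1066 and 21.2 with EDTA). Regions higher in both relative to the totals were nearest to Adgre5 (811 and 2486, and 1817 and 1593 with EDTA), Ddhd1 (793 and 1215, and 697 and 1124) and Sdk2 (412 and 717, and 463 and 604). These genes were chosen after their values were seen, from the 12 regions with the largest summed ratios in each direction; the rest of the 12 are not named in this part.

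The strongest region of chromosome 16 among those in the top 5 of a library (29910946 to 29911949) lay 153910 bp from the nearest protein-coding gene. That gene is Hes1, which starts at 30065357, and the region is outside the window used for it above. Its areas were 11737 in WT, 13621 in WT with EDTA, 6544 with the Adam10 inhibitor, 8311 in the knockout and 5146 in the knockout with EDTA. Chromosome 19 had 70.8 regions per 100 protein-coding genes, chromosome 5 had 62.3, chromosome 11 had 49.97, chromosome 13 had 8.93 and chromosome X had 2.80. Intervals of 10 Mb along chromosome 5 varied, also within WT. Its 67 regions from 0 to 10 Mb and 58 regions from 10 to 20 Mb, set beside the other chromosomes, had median log2 ratios of 0.61 and 0.49 with the Adam10 inhibitor against WT, and of -0.28 and -0.97 with EDTA against WT. In the knockout comparisons they stood at -0.31 and -0.02 without EDTA and at 0.01 and 0.26 with EDTA, and the other intervals of the chromosome were all below 0. From 40 to 70 Mb, where each interval held 9 or 10 regions, the values were -0.42, -0.73 and -0.57 with EDTA against WT and -0.47, -0.45 and -0.62 with the Adam10 inhibitor, and the 5 regions from 150 to 160 Mb stood at -1.30 and -0.52. Thus the shift farthest from 0 within a genotype, -0.11 for chromosome 5 as a whole, does not describe each part of it. Chromosome 18 varied within a genotype too: with EDTA against WT its 16 regions from 0 to 10 Mb stood at -0.46 and its 7 regions from 50 to 60 Mb at -0.76, and with EDTA in the knockout the intervals from 20 to 30 Mb, 50 to 60 Mb and 60 to 70 Mb, of 17, 7 and 55 regions, stood at -0.53, -0.55 and -0.35, and the 7 regions from 70 to 80 Mb at 0.44.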
